A study of Mus musculus with 4 samples.

How the data were processed

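Single-cell RNA was measured in 4 droplet libraries from mouse lung tissue of the KPTI lung cancer model, in which an activated Kras allele and loss of Trp53 drive lung adenocarcinoma. The mice also carried a tdTomato allele and INKBRITE, a GFP reporter of p16INK4a. Per the labels' protocols, tissue was digested with collagenase, dispase and DNase, cells carrying CD45, CD31 or EpCAM were depleted, and cells negative for those 3 proteins were sorted into a GFP-positive and a GFP-negative fraction. The titles name 2 numbers, 2470 and 4644OA, with both fractions of each, so there were 2 GFPpos and 2 GFPneg libraries. The series' design text also speaks of tumour cells sorted from digested tumour organoids, without saying which libraries they entered. Spatial data named in that text were not used here. All 4 files hold deposited counts, whole-number UMIs per gene and barcode, with no normalization and no pooling of libraries. Per the file headers, the 2470 matrices were written by Cell Ranger 3.0.1 and the 4644OA matrices by Cell Ranger 5.0.1. The submitters' processing notes name Cell Ranger 2.1.1 and the mm10 build. The gene annotation and any doublet removal before deposit are not given in the sources used here. The 2470 feature tables list 28000 features and include eGFP and tdTomato. The 4644OA tables list 31053 features, with neither reporter.

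Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with scrublet in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) and left out, which left 27582 of 40006 barcodes. Scrublet called 65 cells (1.33%) in 2470 GFPneg, 78 cells (2.00%) in 2470 GFPpos and 0 cells in each 4644OA library. Whether doublets there had been partly removed before deposit is open, but some may remain. Cluster 18 of 4644OA (63 GFPneg and 302 GFPpos cells, median 53290 UMIs) carried Epcam in 97.0% and Col1a1 in 74.8% of its cells. It stayed unnamed and is in no class sum. An alternative chosen after that was seen removed the cells with the highest scores at 0.8% per 1000 barcodes. The 2 libraries of a title number were clustered together, and the title numbers apart, because their annotations differ. Cells were normalised and log transformed, 2000 variable genes were taken (Cdkn2a, Xist, both reporters and mitochondrial genes excluded), and 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2, scikit-learn 1.9.0, resolution 1) gave 32 clusters for 2470 and 32 for 4644OA.

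Clusters were named by the marker genes fixed before the data were examined, from the highest mean scaled marker level, with at least 3 markers detected in 25% of the cluster's cells. The lowest level accepted was first set at 0.25. It was lowered to 0.2 after 4644OA cluster 6 (55 GFPneg and 765 GFPpos cells, led by Saa3 and Ctsk) was left without a name, and that cluster, with cluster 29 (42 and 0 cells), was then called inflammatory-fibroblast-like. Clusters stayed unnamed where no class met that rule, where another class's markers led their 10 top genes (smooth muscle markers were not counted against fibroblast-like clusters, since myofibroblasts share them), or where depth was under 1/3 of the library median with no own marker among those genes. Names end in "-like" because they rest on markers alone. Epithelial-like cells include the tumour cells. Fibroblast-like cells of 2470 GFPneg came mostly from cluster 2 (626 GFPneg and 29 GFPpos cells, median 2779 UMIs), and those of 2470 GFPpos mostly from cluster 1 (64 and 636 cells) and cluster 4 (49 and 513 cells). The alveolar-, adventitial- and peribronchial-fibroblast-like, pericyte-like, smooth-muscle-like and mesothelial-like classes had under 30 cells in at least 1 library, so their planned tests and the planned interaction were not run.

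For each class, UMIs were summed per library, since cells are not replicates. The 2 annotations were joined on 27514 shared gene identifiers, of which 1027 carried another symbol in the other table. The sums were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, and the quasi-likelihood F test of GFPpos against GFPneg with the title number as a block and Benjamini-Hochberg adjustment at 0.05. This leaves 1 residual degree of freedom, and the spread of a gene is borrowed from the others (prior degrees of freedom 19.4 for fibroblast-like, 3.82 for epithelial-like and 3.13 for all cells). The block was fixed before the data were examined, because the labels give both fractions the same number. Deviations from the group means correlated between same-numbered libraries at 0.946 in fibroblast-like, 0.940 in epithelial-like and 0.915 in all cells, across genes. With 2 libraries per group, this shows that the title numbers differ, and not that their fractions came from the same suspension. The same fit without the block was also run. Libraries are replicates here by their titles, and the labels do not say that the numbers are separate animals. With the block, p-values rest on how the GFP difference varies between the 2 title numbers, largely as pooled over genes. That spread may be technical. Exact permutation tests of 2 against 2 libraries cannot go below p = 0.3333, so shares of cells were not tested.

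Gene lists fixed before the data were examined (44 lists, 681 of 684 listed genes matched) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. T cell, B cell and erythroid markers had too few tested genes in fibroblast-like cells and got no list test there. Levels are given as CPM (UMIs scaled to the sum of the library, as edgeR defines it), with TMM in the tables of the fit and without it in those of a single title pair. Within a title pair, log2 fold changes were also computed on CPM with a prior of 1 CPM. Those of a single pair (list medians, counts of genes over 2-fold and the genes with the largest differences) were shifted so that the median gene of at least 10 CPM had 0, so they differ slightly from the ratio of the printed CPM. Gene lists in 1 pair were placed among 10000 random lists of equal size matched on mean expression in 20 bins, which describes those 2 libraries and is no test. Mean log2 fold changes of genes with no counts in 1 library depend on the prior count.

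Free RNA was estimated from 8 epithelial and 7 fibroblast markers. For each library the median ratio of epithelial markers in the fibroblast-like sum to their level in the epithelial-like sum was taken, and the reverse for fibroblast markers. A gene was called open to free RNA where that ratio times its level in the other class could give 50% or more of its level in any library. Shares of cells with a UMI are given with 95% exact Clopper-Pearson intervals, which cover counting error only, and again after thinning each cell to 2000 UMIs, with shallower cells left out. A cell was called cycling with UMIs of at least 2 of 7 cycle markers after thinning. Endothelial, immune and mesothelial cells were also counted without clusters, as cells with UMIs of at least 2 (or 3) of the fixed markers of 1 such type, leaving out 22 of 69 markers that over 5% of the epithelial- or fibroblast-like cells of some library carried.

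The named genes followed a rule fixed before the data were examined. For fibroblast-like cells these were the 10 highest and 10 lowest log2 fold changes among genes past the threshold in the same direction in both pairs with a mean of at least 10 CPM. Cdkn2a, Cdkn1a and Apoe were always named, and up to 4 members per list with the smallest unadjusted p. Other classes had 5 and 5. Mitochondrial, unnamed predicted, Xist and Y-linked genes were passed over. A second rule for single pairs (mean of at least 50 CPM, under 50% open to free RNA, the 10 highest and 10 lowest) was chosen after the data were seen. Positions are those of the reference annotation for mm10, found for 165 of 165 named genes.

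The fit was tested on simulated counts drawn from the real means, with 200 genes changed. For fibroblast-like cells (13810 genes) it recovered 67.3% of genes changed by 1 on the log2 scale and 98.0% of those changed by 2, and called 0.0441% of unchanged genes. For epithelial-like cells (15562 genes) the values were 36.0%, 96.9% and 0.0325%, and for all cells (16713 genes) 19.0%, 97.0% and 0.0787%. In the simulation all genes of a class shared a common dispersion, and changed genes had the same fold in both pairs. The real data need not meet either condition, so these rates may not hold for them. Of 100 unchanged lists, 4 fell outside the central 95% of random lists, and a shifted list fell at the 100th percentile. Alternatives were DESeq2 1.42.0 with the block, RLE size factors, no filter, each library left out, stricter cell filters (1000 genes, 5% mitochondrial UMIs), doublets kept, resolutions 0.5 and 2, each library clustered alone, sums thinned to the lowest total and genes matched by symbol. Fits on fibroblast-like cells of at least 5000 UMIs, on genes counted in both pairs, without genes open to free RNA, without alveolar-type-1-like and airway-like cells, with the higher doublet rate, at the first marker level and without fibroblast-like cells of no sub-type were added after the data were seen. Figures were drawn with matplotlib 3.10.9.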

Results

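Fibroblast-like cells made up a larger share of the GFP-positive than of the GFP-negative library in both title numbers of the KPTI lung cancer model. In 2470 they were 1187 of 4837 GFPneg cells (24.5%, 95% exact interval 23.3 to 25.8) and 1930 of 3824 GFPpos cells (50.5%, 48.9 to 52.1). In 4644OA they were 749 of 9271 (8.08%, 7.53 to 8.65) and 2662 of 9650 (27.6%, 26.7 to 28.5). The 2470 GFPneg share fell to 11.9% (577 cells) at Leiden resolution 0.5, the 4644OA GFPneg share was 18.0% (GFPpos 39.0%) with the stricter cell filter, and the 4644OA GFPpos share was 19.7% at the first marker level tried. With scrublet doublets kept, the 2470 GFPneg share was 31.2% (1529 of 4902 cells). GFPpos stayed higher in each of these alternatives. Cluster 14 of 2470 (286 GFPneg and 2 GFPpos cells, median 1440 UMIs) scored as fibroblast-like but stayed unnamed by the rule on depth. So did its clusters 24 (14 and 41 cells) and 27 (21 and 20), and none of these cells are in the fibroblast-like shares. Epithelial-like cells, which include the tumour cells, made up a larger share of the GFPneg libraries. They were 47.0% (45.6 to 48.5) of GFPneg and 30.7% (29.2 to 32.2) of GFPpos cells in 2470. In 4644OA they were 59.3% (58.3 to 60.3) and 45.4% (44.4 to 46.4). Mesothelial-like cells, the lining of the pleura, were 455 GFPneg cells (9.41%, 8.60 to 10.3) and 43 GFPpos cells (1.12%, 0.815 to 1.51) of 2470. With the stricter cell filter they were 15.2% and 1.39%. No cluster of 4644OA was named mesothelial-like. Endothelial-like and immune-like cells were 55 and 40 in 2470 GFPneg and 4 and 1 in 2470 GFPpos, and no 4644OA cluster took either name. These counts hold named clusters only. Cluster 3 of 4644OA (28 GFPneg and 1442 GFPpos cells, median 949 UMIs) stayed unnamed because mesothelial markers led its genes: Msln was found in 51.0% and Krt19 in 85.0% of its GFPpos cells, and Upk3b, Wt1, Lrrn4 and Gpm6a in 0. Cluster 11 (409 and 234 cells) stayed unnamed because immune markers led, and 1 of its cells held all 413 of its Jchain UMIs. Clusters without a name held 16.9%, 17.1%, 32.6% and 27.0% of 2470 GFPneg, 2470 GFPpos, 4644OA GFPneg and 4644OA GFPpos, at median depths from 1216 to 1530 UMIs.

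Per the labels' protocol, cells without CD45, CD31 and EpCAM were sorted and split by GFP, so the shares describe the sorted suspensions and not the lung. Epcam transcripts went against that sort, with a UMI in 99.1% of the 815 cells of the largest epithelial-like cluster of 2470 and in 98.5% of the 1494 cells of cluster 2 of 4644OA. The protein itself was not measured here. The intervals cover counting error only. With 2 libraries per group, an exact permutation test cannot go below p = 0.3333, and the shares were not tested.

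**Figure D1:**
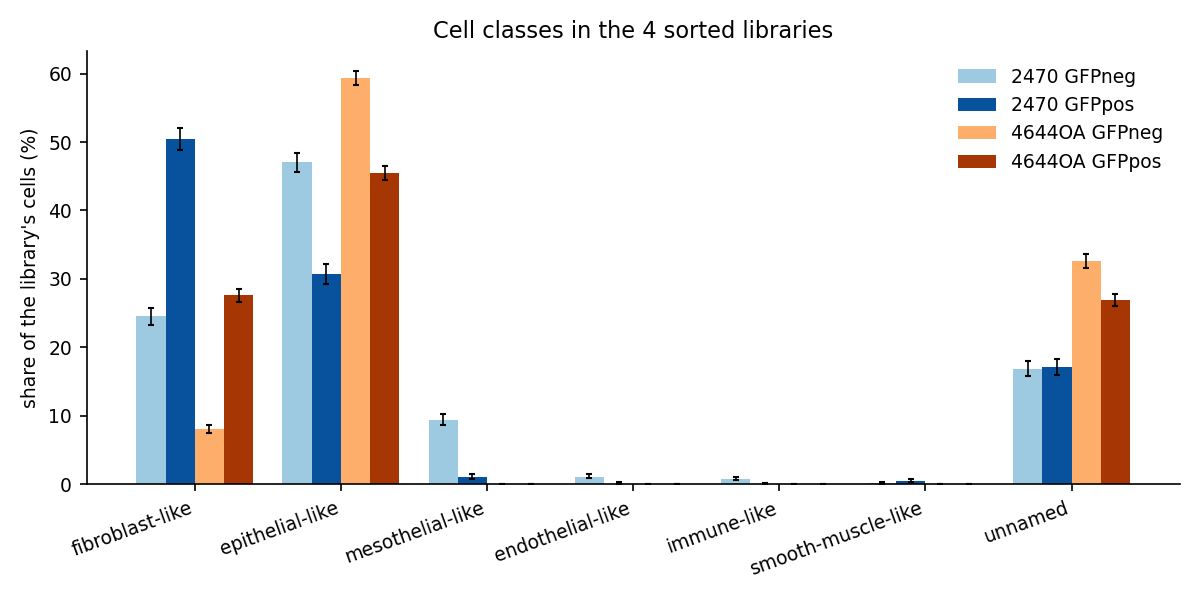
Share of each library's cells (percent, vertical axis) in 7 cell classes, with 95% exact intervals, for GFPneg and GFPpos libraries of 2470 and 4644OA. Fibroblast-like cells were 24.5% and 50.5% in 2470 and 8.08% and 27.6% in 4644OA.

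Alveolar-fibroblast-like cells, which carry Npnt, Tcf21 and Inmt and border the air sacs, were 1082 (91.2%, 89.4 to 92.7) of the GFPneg and 1572 (81.5%, 79.6 to 83.2) of the GFPpos fibroblast-like cells of 2470. Adventitial-fibroblast-like cells, the Pi16 and Dpp4 fibroblasts around vessels and airways, were 81 (6.82%, 5.46 to 8.41) and 340 (17.6%, 15.9 to 19.4). Peribronchial-fibroblast-like cells were 24 (2.02%, 1.30 to 2.99) and 18 (0.933%, 0.554 to 1.47). In 4644OA, inflammatory-fibroblast-like cells, named by a marker list with Saa3 and Lcn2, were 506 (67.6%, 64.1 to 70.9) of the GFPneg and 2318 (87.1%, 85.7 to 88.3) of the GFPpos fibroblast-like cells. Of their clusters, 12 (137 GFPneg and 499 GFPpos cells), 28 (20 and 27) and 29 (42 and 0) had neither gene among their top genes. Fibrotic-fibroblast-like cells were 156 (20.8%, 18.0 to 23.9) and 90 (3.38%, 2.73 to 4.14). They are cluster 24 of 4644OA, led by Akr1c18, Mmp9 and S100b. None of the fixed fibrotic markers, such as Postn and Col8a1, was among its top genes. Cells of no sub-type were 87 (11.6%) and 254 (9.54%). These last are cluster 19, led by the contractile genes Tagln, Acta2 and Myl9, which also lead the smooth-muscle-like cluster of 2470, so their place among fibroblasts is uncertain. No named cluster of either title number carried a sub-type of the other. Cluster 16 of 2470 (40 GFPneg and 142 GFPpos cells, median 20940 UMIs) stayed unnamed, with the fibrotic markers Postn and Col8a1 among its top genes. The GFPneg fibroblast-like cells of 2470 sat mostly in cluster 2 (626 GFPneg and 29 GFPpos cells), whose median was 2779 UMIs, and their median over all clusters was 4008 UMIs against 14769 in GFPpos. In 4644OA the medians were 33733 and 19964.

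Cdkn2a (chromosome 4, 89274471 to 89294653 in mm10), which encodes p16INK4a and p19ARF and whose p16INK4a reporter set the sort, was not higher in fibroblast-like cells of both GFPpos libraries. Its log2 fold change there was 0.36 with a standard error of 0.25 (2 against 2 libraries, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.993), from 3.27 to 1.89 CPM in 2470 and from 56.7 to 96.2 CPM in 4644OA. UMIs of Cdkn2a were found in 22 of 1187 GFPneg (1.85%, 1.17 to 2.79) and 58 of 1930 GFPpos fibroblast-like cells (3.01%, 2.29 to 3.87) of 2470, at the depths given above. In 4644OA the shares were 43.9% (40.3 to 47.6) and 44.2% (42.3 to 46.1). After thinning to 2000 UMIs they were 0.873%, 0.371%, 7.99% and 12.0%, with 156, 42, 11 and 21 cells left out. As background for 2470 alone, 2 of 455 mesothelial-like cells (0.440%) of 2470 GFPneg carried a Cdkn2a UMI at a median depth of 21385 UMIs. The plan had named immune-like cells as background, of which 2470 GFPneg held 40. The mesothelial-like cells were sorted as GFP-negative and may be low in Cdkn2a by that sort, so they are a limited background for GFPpos cells. Free epithelial RNA at the library's ratio could give up to 59.8% of the Cdkn2a level in fibroblast-like cells. Counts at the 3' end do not tell p16INK4a from p19ARF.

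Epithelial-like cells carried most Cdkn2a. The share of epithelial-like cells with a Cdkn2a UMI was 18.2% (16.6 to 19.8) and 20.2% (17.9 to 22.6) in 2470, and 78.5% (77.4 to 79.5) and 89.0% (88.0 to 89.9) in 4644OA, GFPneg first. Thinned shares were 3.73%, 4.88%, 35.4% and 54.3%, with 50, 5, 124 and 38 cells left out. Of thinned mesothelial-like cells of 2470 GFPneg, 0 of 454 carried a Cdkn2a UMI. They give no background for 4644OA and a limited one for GFPpos cells. Cdkn2a differed by 0.41 with a standard error of 0.23 between GFPpos and GFPneg epithelial-like cells (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.864), at 31.6 and 32.8 CPM in 2470 and 472 and 804 CPM in 4644OA. Over all cells the shares were 9.63%, 8.47%, 62.8% and 66.2%, thinned to 2.57%, 1.98%, 33.1% and 39.6% with 787, 443, 2363 and 1599 cells left out.

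**Figure D2:**
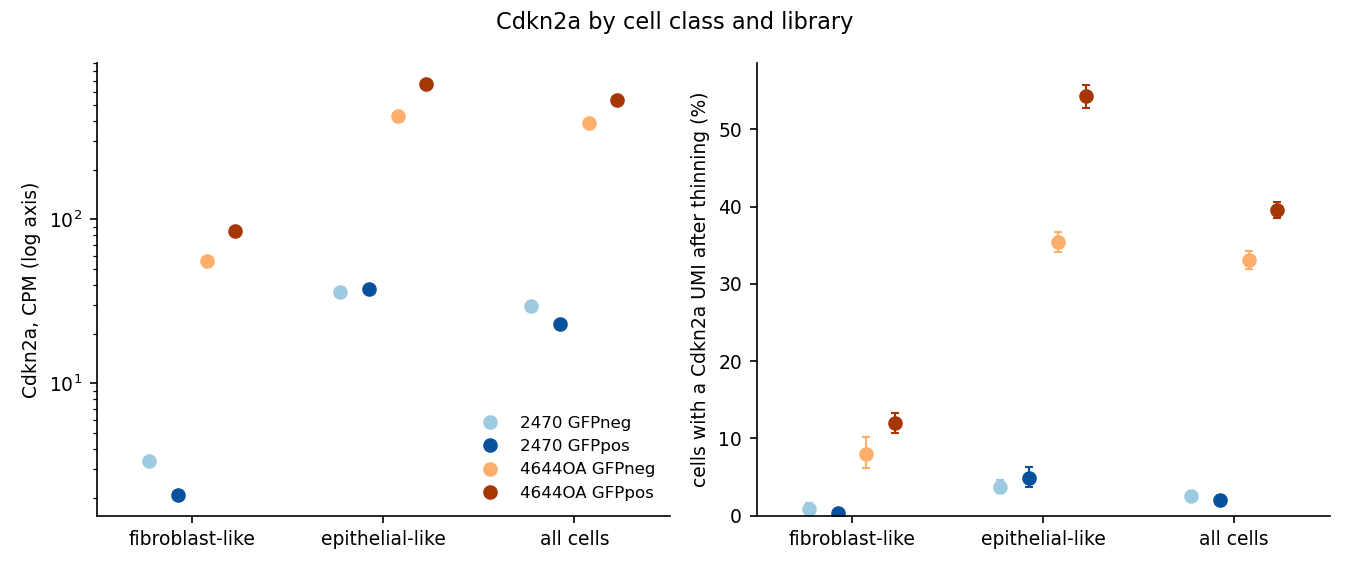
Cdkn2a in CPM (left, log axis) and as percent of cells with a UMI after thinning to 2000 UMIs (right, 95% exact intervals) in fibroblast-like, epithelial-like and all cells of the 4 libraries. In epithelial-like cells the thinned shares were 3.73% and 4.88% in 2470 and 35.4% and 54.3% in 4644OA.

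Il6, Chl1, Ahsg and Il11 were among the genes that rose in GFPpos fibroblast-like cells. Il6 (chromosome 5, 30013114 to 30019981), a cytokine of the senescent secretory programme, rose by 1.48 on the log2 scale (standard error 0.20, adjusted p = 0.00016), from 5.31 to 11.0 CPM in 2470 and from 29.9 to 98.6 CPM in 4644OA. Chl1 (chromosome 6, 103510586 to 103750211), an adhesion molecule of the L1 family, rose by 1.69 (standard error 0.21, adjusted p = 5.22e-05), from 9.80 to 22.5 and from 11.9 to 50.0 CPM. The fetuin gene Ahsg rose by 1.33 (0.20, adjusted p = 0.000573) and Il11, a cytokine of the Il6 family, by 1.09 (0.21, adjusted p = 0.00822). Of the other genes with the largest rise by the same limits of level and direction as for the falls below, Col28a1 rose by 1.16 (0.22), the immunoregulatory Fgl2 by 1.06 (0.26) and the xenobiotic-metabolising Cyp1b1 by 1.05 (0.25). Dspp, a matrix gene of dentin, rose by 2.22 (0.24), the lectin Chodl by 1.20 (0.26) and the cystine transporter Slc7a11 by 1.13 (0.24). Those 3 were near 0 CPM in 2470, with 1, 35 and 11 UMIs in GFPpos and 0 in GFPneg, and their rise rests on 4644OA, where Dspp went from 18.7 to 87.1 CPM. At the first marker level tried for naming clusters, Fgl2, Cyp1b1 and Slc7a11 kept their direction and were not called.

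In all, 32 of 13976 genes rose and 160 fell in fibroblast-like cells (2 GFPpos against 2 GFPneg libraries, edgeR quasi-likelihood with the title number as a block, Benjamini-Hochberg adjusted p under 0.05), with 1055 at unadjusted p under 0.05. Without the block, 0 rose and 0 fell, with 40 genes at unadjusted p under 0.05. At Leiden resolution 0.5, 4 rose and 6 fell, and 6 of the 60 called genes named here kept their call, against 45 at the first marker level tried. DESeq2 with the block called 9 higher and 66 lower, of which 8 and 64 were among the edgeR calls. Of the calls, 24 higher and 141 lower genes were counted in both pairs, and 24 and 139 of them moved the same way in both. The blocked fit tests the mean of both pairs, so it favours such genes, and their agreement is no replication. Free epithelial RNA could give 50% or more of the level of 4 of the higher and 83 of the lower genes. Over 8260 genes, the log2 fold changes of the 2 pairs correlated at 0.04, and 44.4% had the same sign.

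Aspn, Nes, Ncam1, Tgfbi and Thbs2 were among the genes that fell in GFPpos fibroblast-like cells. Aspn (chromosome 13, 49544443 to 49567565), a small proteoglycan of peribronchial fibroblasts and myofibroblasts, fell by 1.82 (standard error 0.25, adjusted p = 0.000207, edgeR quasi-likelihood with Benjamini-Hochberg), from 163 to 55.5 CPM in 2470 and from 1.19 to 0.123 CPM in 4644OA. Nes (chromosome 3, 87971078 to 87980451), the intermediate filament nestin of progenitor cells, fell by 1.73 (0.19, adjusted p = 1.68e-05), from 19.7 to 4.99 and from 128 to 44.0 CPM. The adhesion molecule Ncam1 fell by 1.99 (0.34, adjusted p = 0.002), with 2.18 and 1.83 CPM in 2470 and 55.4 and 8.59 CPM in 4644OA, and was not called at the first marker level tried (-0.83, adjusted p = 0.25). Tgfbi, a matrix protein induced by TGF-beta, fell by 1.55 (0.19, adjusted p = 4.68e-05), from 28.1 to 11.0 and from 27.7 to 8.34 CPM. Thbs2, a matricellular thrombospondin, fell by 1.07 (0.18, adjusted p = 0.00214). Of the 10 genes with the largest fall among called genes of at least 10 CPM that moved the same way in both pairs, 7 were open to free epithelial RNA in at least 1 library: Egfl6 (-2.27), Retnla (-2.08), S100g (-1.89), Slco2a1 (-1.83), H2-Aa (-1.79), Ager (-1.67) and Chil1 (-1.65).

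**Figure D3:**
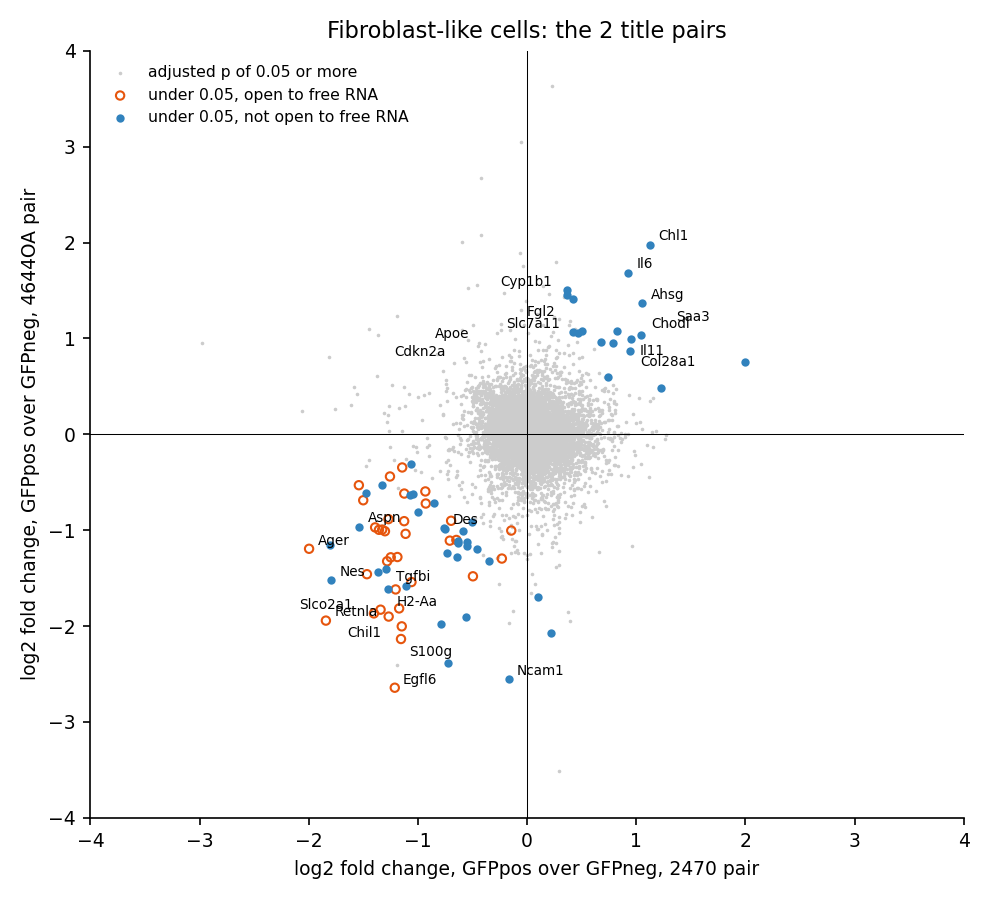
Log2 fold change of GFPpos over GFPneg in the 2470 pair (horizontal) and the 4644OA pair (vertical) for fibroblast-like genes counted in both pairs with a mean of at least 10 CPM. Genes past the threshold are coloured by whether free RNA could give 50% of their level, and Chl1 lay at 1.12 and 1.98, Aspn at -1.54 and -0.96.

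Apoe (chromosome 7, 19696109 to 19699188), the lipid carrier, did not pass in fibroblast-like cells, with a log2 fold change of 0.28 (standard error 0.46, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1), from 3018 to 2314 CPM in 2470 and from 1291 to 2471 CPM in 4644OA. Cdkn1a, the p21 cell cycle inhibitor, differed by 0.007 (0.27, adjusted p = 1). Saa3, the acute-phase serum amyloid, went from 88.5 to 218 and from 829 to 1829 CPM and stayed outside the threshold (log2 fold change 1.22, standard error 0.31, adjusted p = 0.0559, and 2.98e-05 by DESeq2).

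Inflammatory fibroblast markers were higher as a list in GFPpos fibroblast-like cells (camera, 8 genes, adjusted p = 4.38e-12). Of these, Cxcl5 and Ccl7 rose, 0 fell and 6 did not pass, with 4 past the threshold when adjusted over the list alone. The chemokine Ccl7 rose by 0.98 (standard error 0.17, from 21.8 to 39.3 and from 33.7 to 72.2 CPM), and the neutrophil chemokine Cxcl5 by 3.17 (0.49), at up to 8.34 CPM and open to free RNA. The inflammatory cancer-associated fibroblast list (16 genes, Il6 and Ccl7 rose, 14 did not pass, 3 adjusted over the list alone) had an adjusted p of 1.43e-07. NF-kB and acute-phase genes (22 genes, Il6 rose, 21 did not pass, 3 adjusted over the list alone) had 3.33e-06. Among secreted factors of senescent cells, 3 of 39 rose (Il6, Cxcl5, Ccl7), 1 fell (Il1a, by 3.28 with a standard error of 0.51) and 35 did not pass, with 6 adjusted over the list alone and a list p of 0.00179. These 4 lists were not called with an estimated correlation (adjusted p = 0.582 for each) and were called without the block (adjusted p of 1.38e-06, 0.0065, 0.00866 and 0.0288). The lowest marker level that names a cluster had been lowered after the data were seen, which added inflammatory-fibroblast-like cluster 6 (55 GFPneg and 765 GFPpos cells) and cluster 29 (42 and 0) of 4644OA. At the first level, without those cells, the 4 lists had adjusted p of 9.4e-11, 7.24e-09, 2.41e-07 and 0.00208.

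Immediate-early genes of the dissociation response were also higher (20 genes, 0 past the threshold alone, camera adjusted p = 0.000145), with a median log2 fold change of 0.54 in 2470 and 0.09 in 4644OA. The lysosome list (25 genes, 0 called, adjusted p = 0.0266), complement (14 genes, 0 called, adjusted p = 0.0435) and neutrophil markers (3 genes, S100a8 rose by 1.97, adjusted p = 0.0399) were higher as lists over both pairs, with medians of -0.03, 0.008 and -0.28 in 2470 and 0.31, 0.35 and 1.06 in 4644OA. With an estimated correlation the adjusted p was 0.785 for each of these 4 lists. S100a8 went from 25.5 to 106 CPM in 4644OA and lay under 0.3 CPM in 2470. Without the block the dissociation list kept its call (adjusted p = 0.00399), and the lysosome (0.179), complement (0.666) and neutrophil lists (0.981) did not. At the first marker level tried the lysosome list was not called (0.074), S100a8 was not called, and the neutrophil list had too few tested genes. With the cells of no sub-type left out, complement was not called (0.0625) and the neutrophil list again had too few.

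Peribronchial fibroblast markers were lower as a list in GFPpos fibroblast-like cells, with none open to free RNA (8 genes, 6 fell, 0 rose, 8 adjusted over the list alone, camera adjusted p = 1.6e-21). Aspn, the stem cell marker Lgr6 (-2.94), the muscle gene Mustn1 (-0.80) and the growth factor Fgf18 (-1.19) were among the 6. Smooth muscle markers were lower (8 genes, adjusted p = 0.000386), with Myh11 (-1.09), Actg2 (-0.86) and Des (-0.88) down, Cnn1 (1.36) up, 4 not past the threshold and 6 called when adjusted over the list alone. With the cells of no sub-type left out, Cnn1 differed by 0.15 (adjusted p = 1) and the myofibroblastic list was lower (camera adjusted p = 2.25e-07). Des, the muscle filament desmin, went from 146 to 85.6 and from 189 to 95.7 CPM. The peribronchial and smooth muscle lists had a camera adjusted p of 0.582 with an estimated correlation, which was not run with the cells of no sub-type left out. In alveolar-fibroblast-like cells of 2470 alone, the median peribronchial log2 fold change was 0.20 over the 6 genes with enough counts, against -1.08 over 8 genes in all fibroblast-like cells of that pair. Pericyte markers (8 genes, Cox4i2, Trpc6 and Cspg4 fell, adjusted p = 0.00192) had medians of 0.12 in 2470 and -0.77 in 4644OA, and fibrotic markers (7 genes, 0 called, 4 adjusted over the list alone, adjusted p = 0.0252) 0.12 and -0.67. Their adjusted p was 0.785 with an estimated correlation, and without the block 0.454 for pericyte and 0.026 for fibrotic markers. At the first marker level tried, fibrotic markers were not called (0.0516). The unnamed cluster 16 of 2470 (40 GFPneg and 142 GFPpos cells) had Postn, Col8a1 and the pericyte marker Pdgfrb among its top genes. It is in no class sum, so these list results do not cover its cells.

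Markers of other cells moved with these lists. Alveolar type 2 genes were lower in GFPpos fibroblast-like cells (14 genes, 9 fell, 0 rose, 12 adjusted over the list alone, camera adjusted p = 7.18e-41), as were epithelial markers (12 genes, 5 fell, 9 adjusted over the list alone, adjusted p = 1.03e-27). The antigen-presenting fibroblast list was lower too (9 genes, Cd74, H2-Aa, H2-Eb1 and H2-Ab1 fell, 7 adjusted over the list alone, adjusted p = 4.39e-14). Free epithelial RNA could give 50% or more of the level of 12, 12 and 7 of these genes. The markers that set the ratio are all in the epithelial list and partly in the alveolar type 2 list. Those genes come out open by construction, so the first 2 counts are no independent sign of free RNA. The median ratio of epithelial markers was 5.62% and 2.27% in 2470 and 4.83% and 3.56% in 4644OA, GFPneg first. Mesothelial markers (8 genes, 4 fell, 4 adjusted over the list alone, adjusted p = 2.61e-18) and endothelial markers (4 genes, Kdr fell by 4.49, 2 adjusted over the list alone, adjusted p = 0.000145) were lower, with Gpm6a, Wt1, Lrrn4 and Upk3b under 0.5 CPM in GFPpos. Their medians were -1.54 and -0.47 in 2470 and 0.01 and -0.18 in 4644OA. At the first marker level tried, mesothelial markers were not called (5 genes, adjusted p = 0.0614). These 5 lists had an adjusted p of 0.582 with an estimated correlation. Macrophage markers (3 genes, 0 called, adjusted p = 0.0192) had 0.771, and the adenocarcinoma plasticity list (15 genes, 11 open to free RNA, Cldn2 rose, 6 adjusted over the list alone, adjusted p = 0.0156) had 0.785, 0.547 without the block and 0.37 without the open genes.

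Cell cycle genes were lower as lists over both pairs, G2 and M phase with 3 of 23 down (Kif11, Top2a, Birc5, 10 adjusted over the list alone, camera adjusted p = 1.78e-10) and S phase with 0 of 20 called (adjusted p = 0.0266). Their adjusted p was 0.785 with an estimated correlation, 17 of the 23 were open to free RNA, and the medians of G2 and M genes were -0.14 in 2470 and -0.89 in 4644OA, those of S phase genes 0.16 and -0.61. Of 41 lists with a test, 8 were higher and 13 lower. With fry no list was called, the lowest adjusted p being 0.201 for the peribronchial list.

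**Figure D4:**
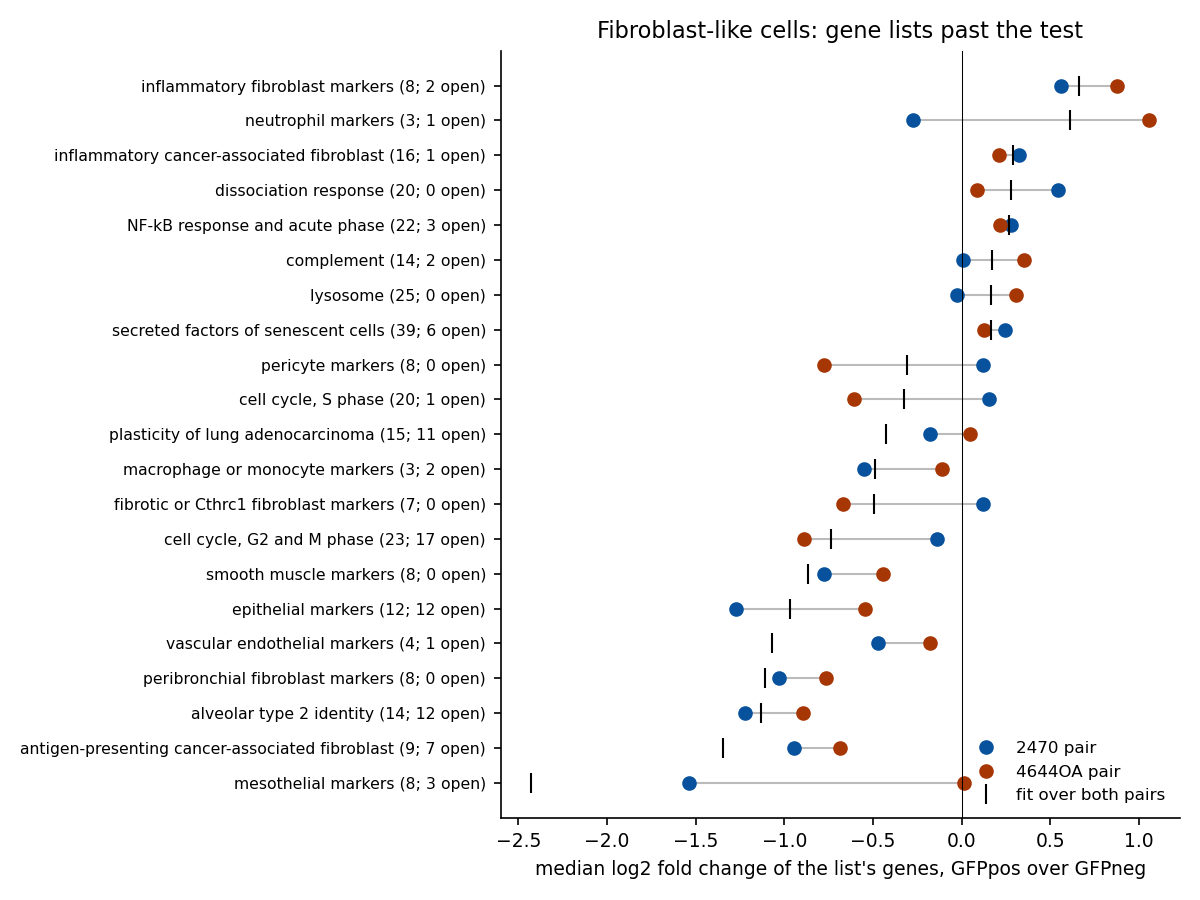
Median log2 fold change (GFPpos over GFPneg, horizontal axis) of each list called by camera in fibroblast-like cells, in the 2470 pair, the 4644OA pair and the fit, with the number of genes and of genes open to free RNA. Inflammatory fibroblast markers lay at 0.56 and 0.88, peribronchial markers at -1.03 and -0.76.

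Lipid, energy, CDK inhibitor and p53 target lists did not pass in fibroblast-like cells. Lipid uptake, storage and transport had 30 genes (Scd1 fell by 1.02, open to free RNA, 29 did not pass, camera adjusted p = 0.68), and cholesterol synthesis (0 of 19 called) 0.814. Fatty acid oxidation (0 of 17 called) had 0.529, glycolysis (0 of 17) 0.307, oxidative phosphorylation (0 of 25) 0.955 and hypoxia (0 of 15) 0.633. CDK inhibitors (0 of 7 called) had 0.851, p53 targets (0 of 23) 0.459 and the antioxidant list (Slc7a11 alone rose of 19) 0.145. Fibrillar collagens and matrix had 28 genes (Col11a1 and Thbs2 fell, 26 did not pass, adjusted p = 0.0551), basement membrane 16 (0 called, 0.522) and the TGF-beta response 20 (Tgfbi fell, 0.0653, and called lower at 0.00199 with the cells of no sub-type left out). The interferon response had 24 genes (Cxcl9 fell, adjusted p = 0.0551). With the genes open to free RNA left out, the collagen (0.0073), TGF-beta (0.0115) and interferon lists (0.00255) were called lower by camera at the preset correlation. The estimated correlation was run only with those genes kept, where it called no list. The unnamed cluster 16 of 2470, with Postn, Eln and Ltbp2 among its top genes, is not in these sums. MHC class I presentation had 12 genes (0 called, 0.356) and the myofibroblastic list 15 (Cnn1 rose, 0.178). Among 24 epithelial niche signals Il6 rose, the Wnt agonist Rspo3 fell by 0.89 and the EGF-family ligand Btc by 1.00 (8 adjusted over the list alone, adjusted p = 0.633). The unfolded protein response (0 of 19 called) had 0.456, alveolar fibroblast markers (0 of 10) 0.764, adventitial markers (Dpp4 fell, 9 did not pass) 0.522 and ribosomal proteins (0 of 81) 0.814.

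Among fibroblast-like genes over 50 CPM, 47 of 2742 differed over 2-fold in 4644OA and 7 of 3133 in 2470, each a comparison of 1 library with 1 and so without a test. Among the genes with the largest differences in 4644OA, Abi3bp went from 14.7 to 173 CPM, the microfibril gene Mfap4 to 119 CPM (log2 fold change 2.64), the iron-binding Lcn2 from 500 to 1884, complement C4b from 73.4 to 193 and the sterol hydroxylase Cyp7b1 from 79.0 to 194. Among the lower genes were the proteases Mmp9 (99.7 to 6.90 CPM) and Mmp13 (1071 to 349), the calcium-binding S100a4 (87.1 to 14.1) and the growth factor Bmp2 (152 to 33.8). In 2470, Saa3 (91.8 to 241 CPM), Serpine1 (111 to 258), Nfkbiz (99.6 to 218) and the TGF-beta inhibitor Smad7 (116 to 247) were highest with the nuclear RNA Malat1. Enpp2 (108 to 38.6), Aspn (169 to 61.5) and the hedgehog-binding Hhip (79.5 to 39.9) were lowest. These genes were among the top genes of peribronchial-fibroblast-like cluster 26 of 2470, at 2.02% of GFPneg and 0.933% of GFPpos fibroblast-like cells. Mmp9 was among those of fibrotic-fibroblast-like cluster 24 of 4644OA (20.8% and 3.38%), and Mmp13, S100a4 and Bmp2 were not. Shifts between sub-types were not separated here from changes inside them.

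Alveolar type 2 genes were lower in GFPpos than in GFPneg epithelial-like cells of 4644OA, a comparison of 1 library with 1 and so without a test. Surfactant protein C, Sftpc, was at 65760 and 18290 CPM, Sftpa1 at 1460 and 486, the phosphate transporter Slc34a2 at 868 and 286 and the desaturase Scd1 at 1917 and 527 (GFPneg first), and 13 of the 14 listed genes were lower (median log2 fold change -0.92). MHC class II genes went the same way, with H2-Aa at 165 and 37.5 and Cd74 at 996 and 388 CPM, and 11 of 12 MHC class I presentation genes were lower (median -0.56). Fatty acid oxidation (16 of 17 lower, median -0.46) and cholesterol synthesis (18 of 19 lower, median -0.37) were lower. Glycolysis genes were higher (16 of 17, median 0.45), such as Gapdh at 4403 and 7138, Pkm at 913 and 1397 and Ldha at 2443 and 3325 CPM. Plasticity genes were higher in 12 of 16 (median 0.29), with Krt7 at 1453 and 2159 and Cldn4 at 98.9 and 167 CPM. The antimicrobial genes Ltf (169 and 892) and Reg3g (19.1 and 128), the chaperone Clu (3289 and 8770) and the progenitor marker Ly6a (767 and 1712) were among the highest, Bpifa1 (510 and 61.2) and Egfl6 (268 and 38.1) among the lowest. Of 5499 GFPneg epithelial-like cells, 1406 were in cluster 2, led by Sftpc, with 88 GFPpos cells. Of 4385 GFPpos epithelial-like cells, 1097 were in cluster 1, with 426 GFPneg cells. Most cells of each fraction were in other clusters.

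In the 2470 pair the alveolar type 2 list was nearly level, with Sftpc at 137000 and 136900, Scd1 at 3780 and 3787, H2-Aa at 736 and 750 and Krt7 at 552 and 517 CPM (median of the list 0.02). There, all 23 G2 and M genes were higher in GFPpos epithelial-like cells (median 0.44), and 19 of 24 interferon genes were lower (median -0.28). The alveolar type 1 genes Igfbp2 (120 and 4.87 CPM), Rtkn2 (80.2 and 19.9) and Hopx (278 and 101) were among the genes with the largest fall. No list of alveolar type 1 genes was fixed or tested. Alveolar-type-1-like cells were 235 (10.3%, 9.11 to 11.7) of the GFPneg and 7 (0.596%, 0.240 to 1.22) of the GFPpos epithelial-like cells. Cluster 13 (203 GFPneg and 121 GFPpos cells), led by Cldn18 and Akap5, with the alveolar type 1 genes Aqp5 and Ager among its top genes, got no sub-type and is not in these shares. The airway secretoglobins Scgb1a1 (6028 and 11601 CPM) and Scgb3a2 (58.6 and 224) were among the genes with the largest rise, and no list of them was tested. Both were among the top genes of cluster 19 (115 GFPneg and 52 GFPpos cells), which got no sub-type.

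**Figure D5:**
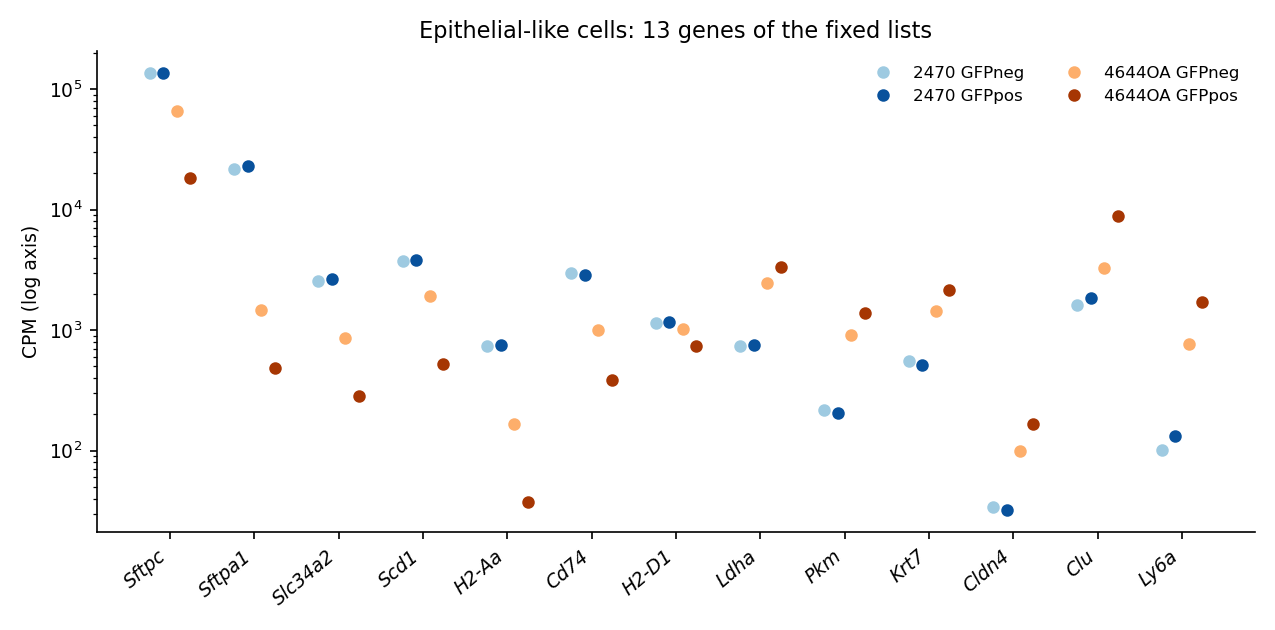
Level of 13 genes in epithelial-like cells (CPM, log axis) in the 4 libraries. Sftpc was at 65760 and 18290 in 4644OA and at 137000 and 136900 in 2470, GFPneg first.

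Over both pairs no gene was called in epithelial-like cells (15737 genes, edgeR quasi-likelihood with the block, Benjamini-Hochberg adjusted p under 0.05, 785 at unadjusted p under 0.05), and DESeq2 called 108 higher and 26 lower. Apoe differed by 0.62 (standard error 0.31, adjusted p = 0.864) and Cdkn1a by -0.29 (0.15, adjusted p = 0.864). Of 42 lists with a test, 18 were higher and 6 lower. Secreted factors of senescent cells were higher (40 genes, 15 open to free RNA, camera adjusted p = 1.48e-21, and 3.3e-06 without the open genes), as were the inflammatory cancer-associated fibroblast list (16 genes, 11 open, 9.24e-27 and 0.000155) and NF-kB and acute-phase genes (22 genes, 5 open, 1.5e-05 and 0.00895). Without the block these 3 had 1.27e-21, 8.39e-25 and 7.58e-06, and with an estimated correlation 0.65 each. Alveolar type 2 genes (camera adjusted p = 4e-04), fatty acid oxidation (0.000889), cholesterol synthesis (0.014), MHC class I presentation (0.00253) and the interferon response (4.03e-06) were lower, and glycolysis (0.0129), ribosomal proteins (2.34e-06) and G2 and M genes (0.000961) higher, with 0 genes called in each. Most of these lists moved in 1 pair. The medians in 2470 and 4644OA were 0.02 and -0.92 for alveolar type 2 genes, -0.03 and -0.46 for fatty acid oxidation, 0.03 and -0.37 for cholesterol synthesis and -0.007 and -0.56 for MHC class I presentation. They were -0.28 and -0.40 for the interferon response, -0.04 and 0.45 for glycolysis, 0.04 and 0.36 for ribosomal proteins and 0.44 and -0.13 for G2 and M genes. With an estimated correlation the adjusted p was 0.723 for each of these 8 lists, except 0.65 for the interferon response. Without the block, cholesterol synthesis (adjusted p = 0.0531), glycolysis (0.204) and G2 and M genes (0.0577) lost their calls. Collagens and matrix (median 1.03, camera adjusted p = 2.14e-46, and 0.65 with an estimated correlation) were higher, and 21 of those 27 genes were open to free fibroblast RNA. This list holds Col1a1, Col1a2, Col3a1, Dcn and Lum, which helped to set the ratio and so come out open by construction. Without the open genes that list was not called (adjusted p = 0.142). The median ratio of fibroblast markers in epithelial-like cells was 0.332% and 1.65% in 2470 and 0.384% and 1.65% in 4644OA, GFPneg first.

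Over all cells of a library, Apoe was at 351 and 961 CPM in 2470 and at 168 and 641 CPM in 4644OA, a log2 fold change of 1.69 (standard error 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.192, and 5.87e-08 by DESeq2). Cdkn2a differed by 0.085 (0.29, adjusted p = 0.945) and Cdkn1a by -0.33 (0.37, adjusted p = 0.789). Of 16895 genes, 0 were called with edgeR (2275 at unadjusted p under 0.05), and 657 higher and 220 lower with DESeq2. The pairs' log2 fold changes correlated at 0.465, and these sums follow the shares of cell classes in each library.

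Cycling cells were mostly epithelial-like. After thinning to 2000 UMIs, at least 2 of 7 cycle markers, such as Mki67 and Top2a, were found in 4.36% (3.55 to 5.29) and 5.05% (3.86 to 6.46) of epithelial-like cells of 2470 and in 10.6% (9.78 to 11.4) and 11.8% (10.8 to 12.8) of 4644OA, GFPneg first. Fibroblast-like cells had 0.0970% (0.00246 to 0.539) and 0.106% (0.0128 to 0.382) in 2470 and 2.30% (1.35 to 3.66) and 1.06% (0.706 to 1.53) in 4644OA. As background for 2470 alone, 0 of 454 mesothelial-like cells of its GFPneg library were called cycling. Over all cells the shares were 2.49%, 1.83%, 8.73% and 7.06%.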

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

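The tests of the 2470 shallow cells, of its fibroblast sub-types and of the airway-like cells were written before their values were computed, and all other tests in this part were chosen after the result was seen.

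Reporter transcripts lie outside the comparisons of the report, because only the 2470 feature tables list them. Transcripts of eGFP were found in 59 of 1187 GFPneg (4.97%, 95% exact interval 3.81 to 6.37) and 372 of 1930 GFPpos fibroblast-like cells (19.3%, 17.5 to 21.1), at 8.75 and 14.7 CPM and median depths of 4008 and 14769 UMIs. After thinning to 2000 UMIs the eGFP shares were 2.33% and 2.65%, with 156 and 42 cells left out, against 0 of 454 mesothelial-like cells of GFPneg thinned alike. Before thinning, eGFP was also found in GFPpos mesothelial-like (5 of 43) and smooth-muscle-like cells (5 of 19) and in GFPneg immune-like cells (3 of 40). In epithelial-like cells eGFP was found in 0.308% (GFPneg) and 0.511% (GFPpos). Transcripts of tdTomato were found in 85.2% (83.7 to 86.6) of GFPneg and 93.5% (92.0 to 94.9) of GFPpos epithelial-like cells, thinned to 33.1% and 36.8%, and in 6.99% and 9.38% of fibroblast-like cells at 13.6 and 6.46 CPM.

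Ribosomal protein genes moved in opposite directions in the 2 pairs of fibroblast-like cells. With TMM factors the signs differed for 81 of 81 genes, such as Rpl22l1 (-0.06 in 2470 and 0.49 in 4644OA) and Rpl13a (-0.51 and 0.08). With the median gene set to 0, 79 of 80 were lower in 2470 and 79 of 81 higher in 4644OA, and this difference between the pairs was not tested.

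Epithelial genes such as Sftpa1, Slc34a2 and Lamp3 fell in GFPpos fibroblast-like cells. Free RNA of the epithelial-like cells is a possible explanation: 8 epithelial markers whose levels span 287 to 675 fold in epithelial-like cells were present in fibroblast-like cells at ratios that differed by at most 2.21 times within a library. Doublets, as a minority of cells, would leave the median cell level and so do not account for all of it. The median fibroblast-like cell's share of UMIs on the alveolar type 2 list differed by -1.55 on the log2 scale in 2470 (95% bootstrap interval -1.61 to -1.46) and by -1.48 in 4644OA (-1.53 to -1.43), and the summed share by -1.10 and -2.02. Each interval covers the sampling of cells in 1 library against 1 and no spread between libraries. The sum of 4644OA fell by more than the median cell, and doublets stay open for that excess, as scrublet called 0 there. Lower expression in the GFPpos fibroblasts themselves cannot be told apart, because only 2 of the alveolar type 2 genes tested are ones that free RNA cannot give.

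The GFP effects of the 2 pairs hardly went together in fibroblast-like cells, with a correlation of 0.0454 over 8271 genes computed with the same steps as the tests. Shallow GFPneg cells of 2470 alone did not account for that, as cells of at least 5000 UMIs gave 0.0782 over 8335 genes. Each cell counts by its UMIs in these sums, so leaving out shallow cells may change the sums little. Other differences in depth, such as the medians of 33733 and 19964 UMIs in 4644OA GFPneg and GFPpos, were not tested. A shift between the named sub-types inside 2470 did not account for the low correlation either, as alveolar-fibroblast-like cells alone gave 0.0108 over 8205 genes. They were already 91.2% of the GFPneg and 81.5% of the GFPpos fibroblast-like cells of 2470, so the sums changed little. Shifts inside that sub-type, and shifts between the sub-types of 4644OA, were not tested. Different cell systems under the 2 title numbers cannot be told apart from a different yield of 1 kind of tissue. Clusters named endothelial-, immune- or mesothelial-like held 598 of 8661 cells (6.90%) in 2470 and 0 of 18921 in 4644OA, but cells with 2 markers of such a type, in clusters with or without a name, were 588 (6.79%) and 40 (0.211%). With 3 markers they were 0.785% and 0.0529%. The share in 4644OA lay between the bounds of 0.1% and 1% set for this test, and the labels do not say which libraries hold organoid cells.

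Alveolar type 2 genes such as Sftpc were lower in GFPpos epithelial-like cells of 4644OA. Free fibroblast RNA, at 1.65% of the fibroblast level, could not lower Sftpc from 65760 to 18290 CPM. The airway-like cluster 23 (66 GFPneg and 192 GFPpos cells) did not account for it, since the median log2 fold change of the list stayed at -0.91 without it. Clusters 22 (96 and 167 cells), 25 (14 and 140) and 30 (6 and 30) also had Scgb1a1, Bpifa1 or Ccdc153 among their top genes. They got no sub-type and stayed in, so airway cells at large were not tested. A GFP-linked change in these tumour cells cannot be told apart from a difference between 2 libraries, as there was 1 title pair of this kind.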

How the results depend on the processing

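No test of causes was run in this part, and the fits on deep cells, on genes counted in both pairs, without genes open to free RNA, without alveolar-type-1-like and airway-like cells, with the higher doublet rate, at the first marker level tried and without fibroblast-like cells of no sub-type were chosen after the data were seen. The 2470 GFPneg fibroblast-like cells were shallow (median 4008 UMIs), every fit with the replicate block had 1 residual degree of freedom, and free RNA limits genes of the other class.

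The 32 higher and 160 lower genes of fibroblast-like cells became 0 and 0 with no replicate block, 98 and 281 with no filter on low counts, 9 and 66 with DESeq2, 80 and 251 with the stricter cell filter and 50 and 433 with each library clustered alone. They became 4 and 6 at Leiden resolution 0.5 and 11 and 56 at resolution 2. The higher genes became 21 with scrublet doublets kept, 54 with doublets removed at the expected rate, 51 when thinned to the lowest library total and 21 among genes counted in both title pairs. The lower genes became 96 with genes open to free RNA left out and 103 at the first lowest marker level (22 higher). The cause was not tested, except that the filters change the genes tested. RLE size factors (23 and 132), genes matched by symbol (38 and 176), cells of at least 5000 UMIs (28 and 141) and leaving out fibroblast-like cells of no sub-type (24 and 134) stayed within 1.5 times. Without the replicate block, 60 of 60 called named genes kept their direction and lost the call, and lists higher went from 8 to 5. With an estimated correlation, and with fry, 0 lists were higher and 0 lower, against 8 and 13. Epithelial-like cells and all cells had 0 calls with and without the replicate block. List calls that it changed are given for the lists named above only. Other lists of epithelial-like cells and the lists over all cells are not given here.

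Epithelial-like cells went from 0 calls to 2 higher with RLE size factors, 108 higher and 26 lower with DESeq2, and 8 and 2 with alveolar-type-1-like and airway-like clusters left out. All cells went from 0 to 657 higher and 220 lower with DESeq2. The mean share of epithelial-like cells in GFPneg libraries went from 53.2% to 63.1% with the stricter cell filter and to 63.3% with each library clustered alone. The cause was not tested.

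Leaving out 1 library in turn leaves 3 libraries and no replicate block, so these 4 fits no longer hold the title numbers apart, and the lone library of a group is assumed to vary like the others. They gave 0 to 0 higher and 0 to 0 lower genes in fibroblast-like cells and 0 to 6 higher in epithelial-like cells (6 without GFPneg 2470). Of 60 called named genes, 32 changed direction in at least 1 of them. Lowest and highest log2 fold changes, for genes turned without GFPneg 2470, were S100g -4.39 to 0.21, Aspn -9.34 to 4.55, H2-Aa -3.93 to 0.12, H2-Eb1 -3.47 to 0.24, Cxcl9 -9.90 to 5.13, Lamp3 -3.13 to 0.35, Sftpa1 -5.01 to 1.94 and Upk3b -9.61 to 6.03. For genes turned without GFPpos 2470 they were Col28a1 -2.36 to 4.93, Fgl2 -0.064 to 2.53 and Rspo3 -5.05 to 2.81, the last 2 also without GFPneg 4644OA. For genes turned without GFPneg 4644OA they were Ncam1 -4.00 to 1.29, Slco2a1 -3.87 to 0.33, Nes -3.90 to 0.35, Il1a -5.72 to 2.08, Col11a1 -10.47 to 1.72, Thbs2 -2.21 to 0.26, Btc -6.12 to 4.54, Top2a -2.83 to 1.29, Birc5 -2.92 to 1.06, Mustn1 -1.91 to 0.29, Actg2 -2.30 to 0.42, Cox4i2 -3.78 to 1.11, Trpc6 -5.50 to 4.19 and Cspg4 -3.64 to 2.05. For genes turned without GFPpos 4644OA they were Dspp -8.05 to 13.36, Il6 -0.70 to 3.40, Chodl -4.24 to 13.31, Slc7a11 -6.00 to 13.43, Il11 -0.35 to 2.59, Cldn2 -1.47 to 3.19 and S100a8 -7.08 to 7.63.

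In other settings the direction turned for Cxcl9 (1.20 at Leiden resolution 0.5, and 0.004 in the 4644OA pair alone), Cnn1 (-0.31 with each library clustered alone) and Trpc6, Cspg4 and S100a8 (0.10, 0.22 and -0.22 in the 2470 pair alone). The cause was not tested. All 60 called named genes kept direction and call with no filter and with genes matched by symbol, 57 with doublets removed at the expected rate, 55 with fibroblast-like cells of no sub-type left out, 54 with the stricter cell filter and 45 at the first marker level. DESeq2 kept 31 of those calls and Leiden resolution 0.5 kept 6. Of the named genes not called, 26 passed the threshold in some alternative. Not run, because the classes had under 30 cells in at least 1 library, were the tests of alveolar-, adventitial- and peribronchial-fibroblast-like, pericyte-like, smooth-muscle-like and mesothelial-like cells, the interaction of alveolar- and adventitial-fibroblast-like cells, and the alternatives of each.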

Other observations

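The tests behind the hypotheses above were named there, and nothing in this part was tested.

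Levels of single genes in fibroblast-like cells differed widely between the title numbers in both fractions, and the genes given here were chosen after their values were seen. The p21 gene Cdkn1a was at 68.8 and 58.4 CPM in 2470 and at 692 and 817 CPM in 4644OA (GFPneg first), the activin gene Inhba at 5.58 and 4.56 against 352 and 174 CPM, the chromatin gene Hmga2 at 0.272 and 0.243 against 176 and 103 CPM, and Ctsk, a collagen-degrading cathepsin, at 78.6 and 84.4 against 662 and 1119 CPM. The alveolar fibroblast genes Npnt (2046 and 1951 against 39.7 and 25.4 CPM), Inmt (2738 and 2292 against 41.3 and 13.4) and Itga8 (956 and 849 against 22.3 and 18.0) ran the other way, as did the collagens Col1a1 (1808 and 2037 against 360 and 381 CPM) and Col3a1 (3156 and 3669 against 221 and 452).

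The title numbers differ in annotation and in Cell Ranger version, so these levels mix biology with processing. Barcodes shared by the 2 libraries of a pair were 101 in 2470 (1.92% of the smaller library) and 62 in 4644OA (0.493%).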
